A study of Macaca fascicularis with 44 samples.

How the data were processed

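RNA of single cells was measured in 44 libraries from 9 cynomolgus monkey embryos (Macaca fascicularis) grown in culture from the blastocyst stage. Per the labels' protocols, embryos were made by injection of sperm into oocytes, expanded blastocysts were chosen for further culture, extraembryonic tissue was removed at dissection, the inner embryonic bodies were digested with TrypLE, and cells were picked by mouth pipette. The same protocols describe scChaRM-seq, an assay that takes RNA and DNA from 1 cell, and total RNA of wild type embryos. Only the RNA was analysed here, and DNA methylation and chromatin data were not used.

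Per the submitters' processing notes, adapters were trimmed with cutadapt 1.15, reads were aligned with STAR 2.6.0a and genes were counted with HTSeq 0.10.0. The deposited count table holds raw counts for 21834 genes in 3682 cells, with no normalization. Its column sums equal the total count that the authors give for each cell in the deposited annotation, in every cell. The genome build, whether a count is a molecule or a read, and how doublets were treated are not given in the sources used here, and no doublet caller was run. The authors' annotation, per the file headers, gives each cell a class (12 names), a cluster number at resolution 2 (26 clusters, numbered up to 27), an embryo, a day and a sex. A deposited pairing table names the DNA library of a cell and its class. Of the genes, 16240 carry a symbol and 5594 only an Ensembl identifier; 15290 of the symbols are in the reference gene table, and 1376 genes had no count in any cell. Genes with near-identical copies may share reads at alignment, so the levels of such families (HOX paralogs less so than hemoglobin, cytokeratin or chorionic gonadotropin genes) are less certain.

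Libraries were grouped by the embryonic day that their title and their time label both give. This held for 42 libraries with 3533 cells. In libraries 26 and 27 (149 cells) the title and the time label name different days, so both were kept out of all groups, trends, contrasts and shares by day or embryo. The totals of all 3682 cells, the pairing with DNA libraries, the fine clusters, the EXMC fractions in EVT and the pooled levels of a class in 1 embryo follow the embryo of the annotation and include them. Libraries carry an 8-digit code at the start of their name; in 6 libraries (8 to 13) the code of the labels differs from that of the cell names. Each day after E16 holds 1 embryo and E16 holds 2. By the annotation E16-1 and the embryos of E18, E21 and E23 are male. E16-2 and the embryos of E20, E22, E24 and E25 are female. Sex thus goes with embryo, was not a term in any fit and cannot be told apart from it. After E16 the libraries of 1 day share an embryo, and the effect of a single day cannot be separated from that of its embryo. Only sums or shares per embryo take the embryo as the unit for a slope of day. The p-values of fits on libraries count libraries of 1 embryo as independent, and mix the spread within embryos with that between them. Groups, tests, gene lists, the naming rule and most alternatives were set before the data were examined.

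Cells are not replicates, so counts were summed per library, or per library and class. Day trends used edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM normalization, estimated dispersions and the quasi-likelihood F test for a slope of day as a number, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Slopes are in log2 per day with their standard error. A class entered a trend with at least 10 cells per library in at least 6 libraries over at least 3 days, which 4 classes met. Mesoderm, Neural ectoderm, Non-neural ectoderm, PS and derivative and STB had too few libraries or days, and the remaining classes too few cells. Class contrasts set each of 8 classes (at least 10 cells per library in at least 3 libraries) against the mean of the others with the library as a block, again with the edgeR quasi-likelihood test but with the dispersion estimated inside the fit, and adjusted over all genes and contrasts. Differences between the slopes of a pair of classes were tested in a joint fit of both classes with a class by day term and no library block, and again with the embryo or the library as a term. CPM in the text are counts over the total of the library, class sum or pooled cells, without TMM; the naming rule uses CPM scaled by TMM. Fitted folds of genes near 0 CPM in a class depend on the prior count and are not bounds.

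The gene lists comprise 18 lists of cell type markers and 15 functional lists, with 341 genes in all, of which 316 are in the count table. The authors may have named the classes from the same expression values, so across classes only the functional lists were tested. This does not remove the circle, since functional genes may also have shaped the clusters behind the classes. Their p-values across classes are therefore descriptive and no test against chance. Lists were tested against day with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, for lists with at least 3 tested members, and again with an estimated correlation and with fry. Camera compares a list with the other genes; fry tests whether its members move, on balance, in 1 direction. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone.

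Genes named in the text follow a rule. In each trend, among genes with a symbol, adjusted p under 0.05, a mean of at least 10 CPM in the highest day and the same sign in a fit with the library code as a term, the 6 largest positive and 6 largest negative slopes are named for all cells and for the class with the most libraries (EXMC), and 3 and 3 for the other classes. Added to these are, for each list, the up to 3 members with the smallest p past the threshold. Across classes, the up to 3 members of each functional list with the largest called fold are named. Of the genes that meet the rule, 151 over the 5 trends and 43 pairs of gene and class are reported here; the others are not reported here. WNT8A, LHX1, EOMES and OGN were chosen from these for a plot after their values were seen.

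Shares of a class among the cells of a library were related to day with Pearson's r and Spearman's rho, two-sided permutation tests with 100000 resamples (exact enumeration below 10 values) and Benjamini-Hochberg over the classes. Shares of pooled cells carry exact binomial (Clopper-Pearson) intervals at 95%, and a share of 0 carries the limit that 3 cells would give. Intervals and limits cover counting error only. Total counts per library ran from 4393315 to 30568931, cells per library from 22 to 96, and counts per cell from 871 to 2831708 with a median of 110457.5 and a median of 4877.5 genes. Fits were tested on simulated data: with 100 changed genes per size, a slope of 0.5 was recovered for 99% of them in all cells, 97% in EXMC, 84% in CTB, 86% in EVT and 12% in Extraembryonic Mesoderm, and a slope of 0.25 for 73%, 68%, 44%, 25% and 0%. In a simulated contrast of Mesoderm over 2500 genes, a log2 fold of 1 was recovered for 41% and of 2 for 88%. The simulated counts held no effect shared by libraries of an embryo. These rates therefore do not cover differences between embryos.

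Alternatives were DESeq2 1.42.0 size factors and its Wald test, no filter on low counts, the library code as a term or as a random block in limma-voom, early against late days, the 2 unassigned libraries added by title or by time label, each day or library left out, 5 or 20 cells in place of 10, and cells thinned to 10000 counts, which leaves out 200 cells. Added after the data were seen were the embryo or library as a term in the joint fits, the code of the cell names as a term, the embryo as a random block, sums per embryo, class contrasts without PS and derivative or without each Neural ectoderm library, and EVT without cluster 18 or cluster 7. With the library code as a term, only days that share a code set the slope. In CTB and EVT these are E24 and E25, and in Extraembryonic Mesoderm E21 and E22. The sign of that fit, also in the naming rule, there compares 2 embryos and is not a slope over all days. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for shares and plots.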

Results

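The cells of these cultured monkey embryos fell into 12 classes named by the authors, and extraembryonic tissue made up most of them. Extraembryonic mesenchyme (EXMC) held 1185 of 3682 cells (32.2%), extravillous trophoblast (EVT) 566 (15.4%), cytotrophoblast (CTB) 549 (14.9%) and Extraembryonic Mesoderm 474 (12.9%). Embryonic classes were smaller: Mesoderm 231 cells (6.27%), PS and derivative, the class of the primitive streak, 228 (6.19%), Non-neural ectoderm 121 (3.29%), epiblast (EPI) 79 (2.15%), Endoderm 62 (1.68%) and Neural ectoderm 59 (1.60%). Syncytiotrophoblast (STB) held 111 cells (3.01%) and Blood cells 17 (0.462%). Although extraembryonic tissue was removed at dissection, the 3 trophoblast classes made up 33.3% of all cells (95% interval 31.8 to 34.8) and EXMC with Extraembryonic Mesoderm 45.1% (43.4 to 46.7), intervals of counting error only.

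The classes stood in different embryos. PS and derivative cells were 189 of the 208 cells of embryo E16-1 (90.9%, 86.1 to 94.4) and 37 of the 272 cells of E16-2 (13.6%, 9.76 to 18.3), where EXMC made up 69.1% (63.3 to 74.6). Neural ectoderm, the origin of the neural tube, was found almost only in the embryo of E22, with 57 of 529 cells (10.8%, 8.26 to 13.7), beside Mesoderm with 170 (32.1%, 28.2 to 36.3), Extraembryonic Mesoderm (37.2%, 33.1 to 41.5) and Non-neural ectoderm (8.88%, 6.60 to 11.6). Non-neural ectoderm also made up 68 of the 547 cells of E23 (12.4%, 9.78 to 15.5). Single Neural ectoderm cells came from E18 (0.267%) and E21 (0.227%), and none was seen in E23, which allows up to 0.548%, in E24 (up to 1.61%) or in E25 (up to 0.656%). Epiblast and Endoderm cells had their highest shares in E18 (6.13% and 6.93%). Trophoblast classes ranged from 0.962% of cells in E16-1 and 4.73% in E22 to 61.3% in E24 and 68.9% in E20. Mesenchyme and Extraembryonic Mesoderm ranged from 3.37% in E16-1 to 76.6% in E21. These shares are over the libraries with agreeing labels.

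**Figure D1:**
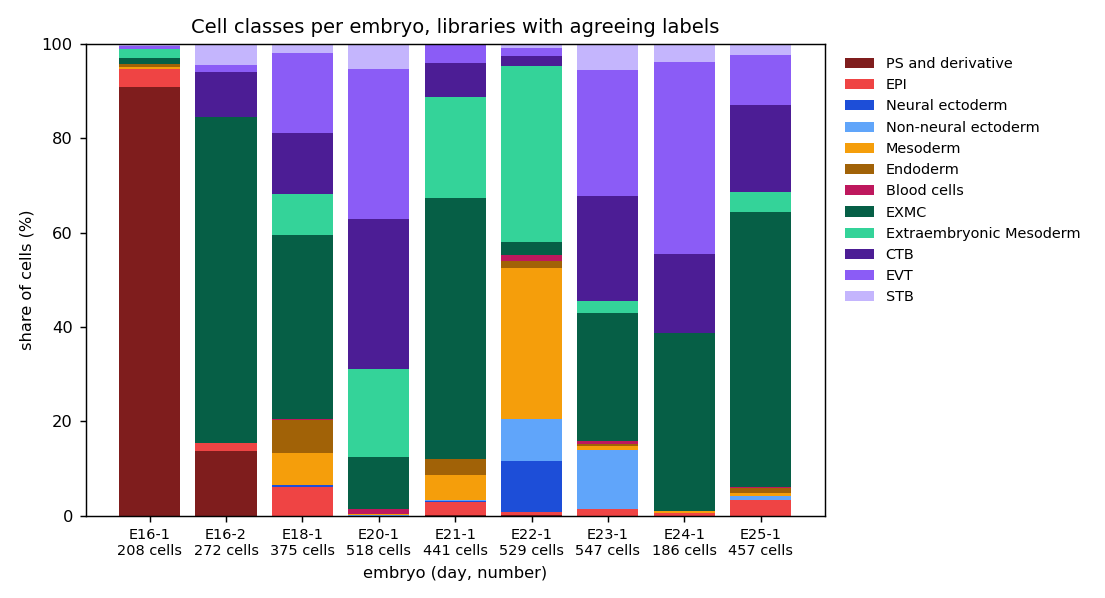
Share of the 12 classes named by the authors among the cells of each of 9 embryos (x axis, ordered by day; y axis, percent of cells; 1 stacked bar per embryo). PS and derivative makes up 90.9% of E16-1 and 13.6% of E16-2, and Neural ectoderm 10.8% of E22.

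Across the 42 libraries with agreeing labels, 2 of the 12 classes changed in share with day. PS and derivative fell (rho = -0.597, permutation adjusted p = 0.00024; r = -0.590), from a mean of 57.4 ± 41.3% (SD, 7 libraries) at E16 to 0.238% at E21 and 0.187% at E22. No such cell was seen in E18 (which allows up to 0.8%), E20 (0.579%), E23 (0.548%), E24 (1.61%) or E25 (0.656%), so the relation sets E16 against the later days. Non-neural ectoderm rose (rho = 0.614, permutation adjusted p = 0.00024; r = 0.427, adjusted p = 0.0302), to 8.97 ± 2.13% at E22 and 12.5 ± 2.59% at E23, with 0.860% at E25 and none in the 186 cells of E24, which allows up to 1.61%. Its r lost the call without E23 (adjusted p = 0.356), without E16 (0.317), without E18 (0.130), without E22 (0.0583) and, just past the threshold, under 3 other settings (0.0502 to 0.0578), while its rho kept it in each. For PS and derivative the permutation p of r, 1e-05, was the smallest that the resamples allow (two-sided). None of the other 10 classes passed, with rho from -0.203 (EPI, adjusted p = 0.470) to 0.297 (EVT, adjusted p = 0.227). Over 9 embryos in place of 42 libraries neither class passed (PS and derivative rho = -0.651, exact p = 0.0638, adjusted p = 0.490; Non-neural ectoderm rho = 0.594, adjusted p = 0.490), and without E16 the rho of PS and derivative was -0.0328 (permutation adjusted p = 0.869, against 0.00012 to 0.00372 with the other settings on libraries of all codes). Within single library codes none of the 12 relations passed after adjustment. In code 20210308, which sets 1 library of E16 against 6 of E23, none could pass, since exact p = 0.143 is the smallest possible there (PS and derivative, rho = -1.0, adjusted p = 0.629). PS and derivative had -0.292 in 20210820 (10 libraries, permutation p = 0.399), and Non-neural ectoderm 0.612 in 20210308 (exact p = 0.286), 0.796 in 20210727 (8 libraries, exact p = 0.0357, adjusted p = 0.321) and 0.429 in 20210820 (permutation p = 0.231). The other codes hold 1 day each.

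In sums of all cells of a library, genes of the primitive streak fell together with day while genes of the extraembryonic mesenchyme rose. All 9 tested members of the primitive streak list fell, and none rose. WNT8A, a WNT ligand of the streak, had 86.9 ± 81.3 CPM (SD, 7 libraries) at E16 and at most 2.13 ± 3.004 in any later group. LHX1, a homeobox gene of the streak and node, had 178.3 ± 188.6 and at most 7.26 ± 10.3. EOMES, a T-box gene of mesoderm and endoderm formation, had 62.8 ± 31.3 and at most 3.54 ± 3.53. OGN, which encodes a small proteoglycan of the matrix, had 0.642 ± 0.556 CPM at E16 and 543.1 ± 130.7 at E25, with no steady course between (16.1 at E18, 2.81 at E20, 58.7 at E21, 18.4 at E22, 71.6 at E23 and 67.1 at E24). Levels of WNT8A and LHX1 differed between the E16 embryos (144.7 and 278.1 CPM in the pooled cells of E16-1, 26.999 and 31.2 in E16-2), as did the share of the PS and derivative class.

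With a day slope in each of 13174 genes, 2435 passed (1087 up, 1348 down; edgeR, adjusted p < 0.05; 4212 at unadjusted p < 0.05). Values in brackets after a gene are slopes in log2 per day ± SE. Among genes of at least 10 CPM that keep their sign with the library code as a term, falls were largest in WNT8A (-0.98 ± 0.14, adjusted p = 2.34e-06), PDYN, the precursor of dynorphins (-0.93 ± 0.20), KHDC3L, an oocyte and early embryo gene (-0.84 ± 0.12), and ALAS2, the erythroid enzyme of heme synthesis (-0.81 ± 0.16). They were followed by MMP3, a matrix metalloprotease (-0.80 ± 0.16), LHX1 (-0.79 ± 0.12) and EOMES (-0.79 ± 0.13). Among the same genes the largest rises were in OGN (0.84 ± 0.10, adjusted p = 1.25e-07), OIT3 (0.83 ± 0.20), SLC10A1, a bile acid transporter (0.78 ± 0.20), DHRS9, a retinol dehydrogenase (0.75 ± 0.13), GAST, the gastrin gene (0.73 ± 0.14), and DEFB1, a defensin (0.67 ± 0.10). Sums of all cells also change with the share of each class, which was not separated here from change within a class. WNT8A, LHX1 and EOMES are among the leading genes by fold of the PS and derivative cluster. So are GAST, SLC10A1 and DHRS9 in the STB cluster and OIT3 in the Blood cells cluster. Without E16, 1089 genes passed, and of the 66 genes named for this trend 47 lost the call and 6 turned direction, WNT8A (0.36) among them. WNT8A also turned with the code of the cell names as a term (0.25). With counts summed per embryo, 0 of all genes passed in edgeR (1412 at unadjusted p < 0.05), against 197 in limma-voom with the embryo as a block and 2957 in the DESeq2 Wald test on libraries.

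Several embryonic lists held falling genes. Of the epiblast list 4 of 9 fell and none rose, among them the pluripotency genes SALL4 (-0.27 ± 0.05), DNMT3B (-0.26 ± 0.05) and DPPA4 (-0.26 ± 0.06). In the paraxial mesoderm list 2 of 6 fell, MESP1 of the nascent mesoderm (-0.75 ± 0.12) and the NOTCH ligand DLL3 (-0.30 ± 0.06). In the definitive endoderm list 4 of 8 fell (6 over the list alone), with FOXA2 (-0.43 ± 0.13), FOXA3 (-0.33 ± 0.09) and CXCR4 (-0.23 ± 0.07). Of 31 HOX genes 12 fell (15 over the list alone) and none rose, with HOXA3 (-0.68 ± 0.14) and HOXB6 (-0.40 ± 0.08). Within single classes no HOX gene passed over all genes. Their median slope was -0.00014 in EXMC, -0.20 in CTB, 0.24 in EVT and 0.31 in Extraembryonic Mesoderm. The neural ectoderm list was mixed, with CDH2, the neural cadherin (-0.38 ± 0.07), and the intermediate filament gene NES (-0.20 ± 0.05) down and the homeobox gene LHX2 up (0.20 ± 0.07, adjusted p = 0.0377). Against the other genes these lists moved down in camera: primitive streak (adjusted p = 4.92e-09; adjusted p = 0.192 with an estimated correlation), HOX (2.23e-05; adjusted p = 0.361 with an estimated correlation), definitive endoderm (0.000869; adjusted p = 0.246 with an estimated correlation), epiblast (0.000953; adjusted p = 0.246 with an estimated correlation) and neural ectoderm (0.0357; adjusted p = 0.273 with an estimated correlation). ALAS2 was the only erythroid gene tested.

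Signalling and growth lists also moved. Of 9 WNT targets 5 fell (6 over the list alone), with SP5 (-0.55 ± 0.09), LGR5 (-0.49 ± 0.08) and TCF7 (-0.18 ± 0.04), and camera gave adjusted p = 0.0138 (adjusted p = 0.192 with an estimated correlation). Of the NODAL targets NODAL itself (-0.49 ± 0.12) and GSC (-0.48 ± 0.13) fell (camera, list down, adjusted p = 0.0294, adjusted p = 0.248 with an estimated correlation). Of 7 FGF targets 3 fell (6 over the list alone), ETV4 (-0.22 ± 0.06), ETV5 (-0.19 ± 0.05) and the phosphatase gene DUSP6 (-0.15 ± 0.04; camera adjusted p = 0.00549, adjusted p = 0.192 with an estimated correlation). Single members fell in the BMP (MSX1, -0.43 ± 0.07; 1 of 9) and NOTCH lists (DLL3; 1 of 6). Of 9 genes of the DNA methylation machinery 3 fell: DNMT3B, DNMT3A, a de novo methyltransferase (-0.11 ± 0.03), and UHRF1, which recruits DNMT1 (-0.18 ± 0.04). In the trends of single classes no member of this list fell, and 1 rose in Extraembryonic Mesoderm. Of 12 proliferation genes 8 fell, with the replication genes MCM5 (-0.15 ± 0.04), MCM2 (-0.14 ± 0.03) and PCNA (-0.12 ± 0.03; camera adjusted p = 0.000162, adjusted p = 0.248 with an estimated correlation). This list turned direction in camera with the library code as a term (adjusted p = 0.595). The retinoic acid list split, with the synthesis enzyme ALDH1A2 down (-0.47 ± 0.10) and the receptor RARB (0.34 ± 0.06) and DHRS3 (0.14 ± 0.03) up, 3 of 8 up and 2 down in all.

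Extraembryonic and stress lists held rising genes. Of 10 extraembryonic mesenchyme genes 4 rose (8 over the list alone) and none fell, with TCF21, a mesothelial and mesenchymal factor (0.37 ± 0.06), and the collagen genes COL6A1 (0.24 ± 0.07) and COL1A1 (0.23 ± 0.07; camera adjusted p = 2.11e-07, adjusted p = 0.246 with an estimated correlation). Of 10 immediate early and heat shock genes, which respond to dissociation, 7 rose and 1 fell, with ATF3 (0.19 ± 0.05) and EGR1 (0.19 ± 0.04) up and HSPH1 (-0.14 ± 0.03) down (camera adjusted p = 0.000162, adjusted p = 0.247 with an estimated correlation). Of 12 hypoxia and glycolysis genes 4 rose, with NDRG1 (0.22 ± 0.06), P4HA1 (0.20 ± 0.06) and VEGFA (0.17 ± 0.05). Lateral plate genes went both ways (2 of 10 up, 3 down), with TBX5 (0.39 ± 0.09) up and HAND1 (-0.27 ± 0.06) down. So did the epithelial to mesenchymal transition list (4 of 10 up, 2 down), with ZEB2 up (0.18 ± 0.03) and CDH2 and SNAI1 (-0.11 ± 0.02) down. The p53 list split as well, with SESN1 up (0.15 ± 0.04) and BAX down (-0.07 ± 0.02). Visceral endoderm genes TF, the transferrin gene (0.97 ± 0.31), and FGG, a fibrinogen gene (0.83 ± 0.27), rose (2 of 11). Of 13 amnion genes IGFBP3 alone rose (0.22 ± 0.07; none over the list alone; camera, list up, adjusted p = 0.0170, adjusted p = 0.273 with an estimated correlation). Single members rose in the neural crest (SNAI2, 0.13 ± 0.03), germ cell (KLF4, 0.36 ± 0.09), macrophage (CSF1R, 0.36 ± 0.12), endothelium (EGFL7, 0.15 ± 0.04) and trophoblast lists (PAGE4, 0.29 ± 0.09). No member passed in the node (1 of 3 up over the list alone), megakaryocyte, allantois, hedgehog or neuronal differentiation lists. With the library code as a term 1009 genes passed, 487 of them among the 2435, and slopes of COL1A1, COL6A1, DNMT3B, FGG, FOXA3 and TF turned direction, as did the mesenchyme list in camera (adjusted p = 0.942).

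**Figure D2:**
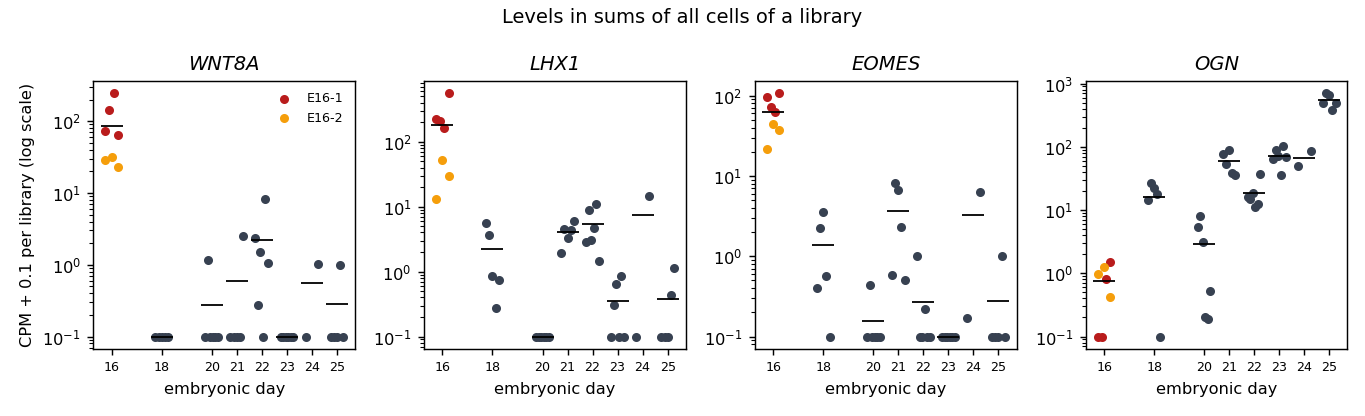
Levels of WNT8A, LHX1, EOMES and OGN in sums of all cells per library (y axis, CPM plus 0.1 on a log scale; x axis, day; points are libraries, with E16-1 in red and E16-2 in orange; bars are means). WNT8A falls from a mean of 86.9 CPM at E16 and OGN reaches 543.1 CPM at E25.

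Within the extraembryonic mesenchyme (EXMC, 28 libraries from 7 embryos), the matrix genes OGN and POSTN rose and the lateral plate genes HAND1 and MYL7 fell. OGN (0.67 ± 0.09, adjusted p = 3.23e-05), COCH of the inner ear matrix (0.64 ± 0.11), the matrix gene PODN (0.61 ± 0.14), CDR1 (0.64 ± 0.11), DEFB1 (0.60 ± 0.11) and TSHR, the thyrotropin receptor (0.89 ± 0.22), had the largest rises under the naming rule. SPP1, which encodes osteopontin (-0.73 ± 0.09, adjusted p = 5.60e-06), MMP3 (-0.86 ± 0.15), the muscle stress gene ANKRD1 (-0.78 ± 0.11), ALDH1A2 (-0.67 ± 0.17), the streak factor MIXL1 (-0.61 ± 0.12) and LRRN4 (-0.60 ± 0.08) had the largest falls. Without E16 the slopes of HAND1, MYL7, MIXL1 and SPP1 turned direction, and MYL7 lost its call without any 1 of 18 libraries. Of 10 mesenchyme list genes 2 rose (4 over the list alone), POSTN, a matrix gene (0.27 ± 0.05), and TCF21 (0.29 ± 0.07). Among 10 lateral plate genes HAND1 (-0.20 ± 0.05) and the atrial light chain gene MYL7 (-0.38 ± 0.10, adjusted p = 0.0426) fell. CDH2 fell in the neural ectoderm (1 of 3) and transition lists (1 of 9; -0.46 ± 0.08), and MIXL1 in the streak list (1 of 3). CRABP1, which binds retinoic acid, rose (0.43 ± 0.07) while ALDH1A2 fell, and the WNT inhibitor NOTUM rose (0.45 ± 0.11, 1 of 9). In E24 and E25 NOTUM stood at 2293.3 CPM in EVT cells outside fine cluster 18 and 104.1 in EXMC. DEFB1 stood at 1030.3 and 81.5. RNA of EVT in the EXMC sums was not tested as a source of these 2 rises. No member of the other 24 lists passed over all genes; over the list alone 3 BMP targets and 1 epiblast gene were down and 1 gene each of the neural crest and hypoxia lists up.

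In EXMC 190 of 10976 genes passed (90 up, 100 down; 1554 at unadjusted p < 0.05). Camera called the mesenchyme list up (adjusted p = 3.33e-05; adjusted p = 0.263 with an estimated correlation), the immediate early list up (0.0177; adjusted p = 0.540 with an estimated correlation) and the epiblast (0.00246; adjusted p = 0.149 with an estimated correlation) and neural ectoderm lists down (0.00738; adjusted p = 0.149 with an estimated correlation). Fine cluster 6 took 184 of its 202 cells from E16-2 and cluster 9 took 137 of 165 from E23. Other clusters were shared, such as cluster 4 between E18 (51 cells) and E25 (156). ANKRD1 and MMP3 are among the leading genes by fold of cluster 6, and MMP3 also of cluster 10. OGN and COCH are among those of cluster 4 and of cluster 11, which took 95 of 142 cells from E25. Change in the share of clusters was not separated here from change within them. Counts fell to 55 without E16 and to 73, 85 and 74 without library 5, 6 or 7, which are the libraries of E16-2; 472 genes passed with the library code as a term, 103 of them among the 190. Per embryo 0 genes passed in edgeR (372 at unadjusted p < 0.05), against 126 in limma-voom with the embryo as a block and 388 in the DESeq2 Wald test on libraries.

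In cytotrophoblast (CTB, 21 libraries from 6 embryos), proliferation genes fell and OGN, COL8A1 and EPCAM rose. Of 12 proliferation genes 3 fell and none rose: RRM2, a subunit of ribonucleotide reductase (-0.25 ± 0.05), CCNA2 (-0.16 ± 0.04) and MKI67 (-0.13 ± 0.04; camera adjusted p = 0.00575, adjusted p = 0.288 with an estimated correlation). MKI67 lost its call without any 1 of 15 libraries (up to adjusted p = 0.101), CCNA2 without any 1 of 4 (0.0686). Under the naming rule OGN (1.56 ± 0.20, adjusted p = 4.66e-05), the carbonic anhydrase gene CA3 (1.49 ± 0.39) and the collagen gene COL8A1 (1.47 ± 0.39) rose most, and MAPK12 (-0.66 ± 0.17), FKBP5, a glucocorticoid target (-0.66 ± 0.17), and the transporter gene ABCC3 (-0.64 ± 0.14) fell most. Endothelial genes split, with EGFL7 up (0.25 ± 0.06) and CDH5 down (-0.24 ± 0.05; 6 tested). Single members rose in the amnion (IGFBP3, 0.25 ± 0.05; 3 of 13 over the list alone), immediate early (EGR1, 0.19 ± 0.04; 4 of 9 up and 1 down over the list alone) and transition lists (EPCAM, an epithelial adhesion gene, 0.18 ± 0.04; 4 of 8 over the list alone). The platelet gene PPBP, the 1 megakaryocyte gene tested, fell (-1.29 ± 0.37, adjusted p = 0.0496), and lost its call without any 1 of 17 libraries (up to 0.102). Camera also called the transition (adjusted p = 0.0212; adjusted p = 0.288 with an estimated correlation), p53 (0.0189; adjusted p = 0.288 with an estimated correlation) and mesenchyme lists up (0.00575; adjusted p = 0.318 with an estimated correlation), though no member of the p53 or mesenchyme list passed. The transition list turned direction with the library code as a term (adjusted p = 0.941), and no list kept its call. No member of the other 24 lists passed over all genes; over the list alone 3 hypoxia genes and 1 gene each of the neural crest and WNT lists were up. The genes that mark EXMC, OGN among them, stood in CTB cells at a median of 7.54% of their EXMC level in E16-2, 1.44% in E18, 1.08% in E20, 4.73% in E21, 1.99% in E22, 4.06% in E23, 1.54% in E24 and 5.78% in E25. They were chosen in the cells of E24 and E25, with at least 500 CPM in EXMC and at least 10 times the CTB level. Their low level in CTB is therefore set by the choice.

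In CTB 363 of 10794 genes passed (191 up, 172 down; 2066 at unadjusted p < 0.05). Cluster 12 took 137 of 138 cells from E20 and cluster 14 took 112 of 125 from E23, and a shift between clusters was not separated from change within them. Without E25 72 passed, without library 17 184, without 16 209, without 22 215 and without 15 225. Without E20 226 passed, and without E16, which here is library 5 alone, 747. With the library code as a term CDH5, EGFL7 and EPCAM turned direction. In CTB that fit compares only library 20 of E24 with libraries 14 to 17 of E25. Per embryo 0 genes passed in edgeR (713 at unadjusted p < 0.05), against 12 in limma-voom with the embryo as a block and 795 in the DESeq2 Wald test on libraries.

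Genes of the mesenchyme rose with day in the extravillous trophoblast (EVT, 21 libraries from 5 embryos). Of 10 extraembryonic mesenchyme genes 9 rose and none fell (9 and 1 over the list alone), with TCF21 (0.90 ± 0.15), COL1A1 (0.60 ± 0.11) and COL6A1 (0.49 ± 0.08). Lateral plate genes rose as well (5 of 9), among them HAND2 (0.47 ± 0.12) and BMP4 (0.37 ± 0.09). So did 3 of 9 transition genes, VIM, the mesenchymal filament gene (0.65 ± 0.10), SNAI2 (0.61 ± 0.14) and ZEB2 (0.57 ± 0.12). COL1A1 and the other genes that mark EXMC stood in EVT cells at a median of 4.04% of their EXMC level in E18, 4.47% in E20, 42.8% in E21 (20 cells), 4.43% in E22 (9 cells), 23.2% in E23, 19.8% in E24 and 43.3% in E25. In E24 and E21 this counts the libraries with conflicting labels by the annotation's embryo; without them E24 stands at 27.4% and E21 at 40.3%. Fine cluster 18, which holds 36 of its 87 cells in E25, carried the highest levels (61.9% over E24 and E25, against 8.30% in other EVT cells). Without cluster 18 the shares were 21.6% in E23, 7.39% in E24 and 9.62% in E25 (12 cells). That fit holds no library of E25, and 91 genes passed in it (94 without E25 alone) while 21 of the 29 named genes lost the call.

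Further EVT lists moved in part. WNT genes rose in 2 of 6 cases, the inhibitor DKK1 (0.76 ± 0.11) and the factor LEF1 (0.51 ± 0.14), and RSPO3, a WNT agonist of the paraxial list, rose too (0.61 ± 0.13; 1 of 1). Endothelial genes KDR (0.52 ± 0.13) and EGFL7 (0.39 ± 0.11) rose (2 of 7; 3 up and 2 down over the list alone). So did SNAI2 and ETS1 (0.62 ± 0.15) of the neural crest list (2 of 2) and the p53 targets GADD45B (0.40 ± 0.12) and SESN1 (0.26 ± 0.07; 2 of 9, 5 over the list alone). Single genes that rose were BAMBI of the BMP list (0.46 ± 0.09; 1 of 6), CRABP1 of the retinoic acid list (0.86 ± 0.18; 1 of 6) and P4HA1 of the hypoxia list (0.24 ± 0.07; 1 of 11). The largest rises under the naming rule were VTCN1, an immune checkpoint gene of trophoblast and amnion (2.03 ± 0.46), CCN4, a WNT-induced matrix gene (1.46 ± 0.17, adjusted p = 3.97e-05), and MYT1L, a neuronal factor (1.33 ± 0.24). Falls included RBP4, the retinol carrier (-1.19 ± 0.21; 1 of 3 in the visceral list), the lipid droplet gene CIDEC (-1.17 ± 0.24), SLC16A6 (-1.0 ± 0.17). They also included RRM2 (-0.36 ± 0.08) and CCNB1 (-0.22 ± 0.06) of proliferation (2 of 12), the keratin gene KRT7 of the amnion list (-0.33 ± 0.07) and GCM1, a regulator of trophoblast differentiation (-0.19 ± 0.06; 1 of 6, 2 up and 3 down over the list alone). In 14 lists no member passed over all genes, and in 8 of these none over the list alone. CCN4 and DKK1 are also high in EXMC, and RNA or cells of the mesenchyme were not tested as the source of their rises.

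In EVT 677 of 9842 genes passed (420 up, 257 down; 2148 at unadjusted p < 0.05); the rising share was 62.0% with TMM and 72.8% of 691 with DESeq2 size factors. Camera called 5 lists up: mesenchyme (adjusted p = 4.17e-09; adjusted p = 0.0722 with an estimated correlation), lateral plate (2.01e-06; adjusted p = 0.0722 with an estimated correlation), retinoic acid (0.00175; adjusted p = 0.0722 with an estimated correlation), transition (0.00294; adjusted p = 0.0813 with an estimated correlation) and p53 (0.0104; adjusted p = 0.0722 with an estimated correlation). Cluster 19 came wholly from E20 (84 cells) and cluster 7 took 130 of its 196 cells from E23. CIDEC is among the leading genes by fold of cluster 19. A shift between clusters was not separated here from change within them. Cells of cluster 7 had a median of 10199.5 counts and 18.3% mitochondrial counts. Per embryo 10 genes passed, CCN4 and DKK1 among them. Both are also genes of the mesenchyme. CCN4 is among the leading genes by fold of EXMC cluster 11, and DKK1 stood at 385.1 CPM in EXMC. Their calls per embryo therefore do not set a change in EVT apart from mesenchymal RNA or cells in the EVT sums. With the library code as a term 63 passed, 12 of them among the 677, and CRABP1, DKK1, GADD45B, LEF1 and RRM2 turned direction. In EVT that fit compares only the embryo of E24 with that of E25. Without E25 94 passed, without E20 273, without library 17 387 and without library 22 426.

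**Figure D3:**
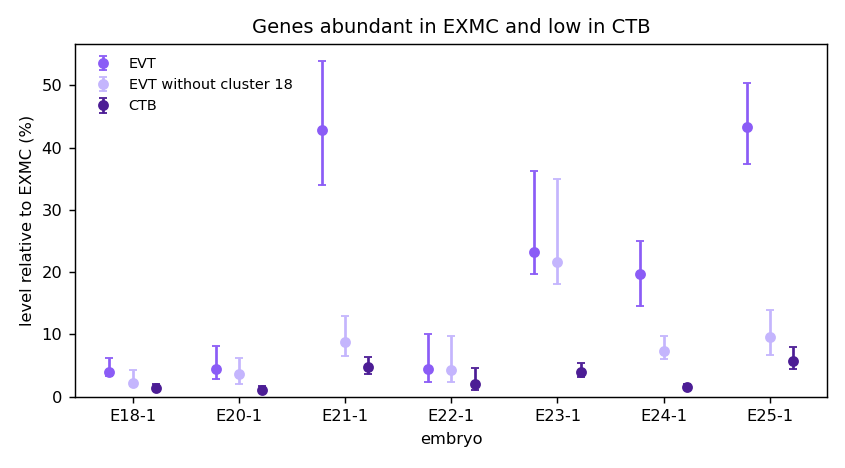
Level of 30 EXMC genes in EVT, in EVT without fine cluster 18 and in CTB as percent of their EXMC level (y axis) in each embryo from E18 to E25 (x axis). Points are medians over genes and bars quartiles. The genes were chosen in E24 and E25 to be abundant in EXMC and low in CTB, so the low CTB points are set by the choice. EVT medians reach 43.3% in E25, and 9.62% without cluster 18; E21 and E24 include the libraries with conflicting labels.

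In Extraembryonic Mesoderm (18 libraries from 4 embryos, E18 to E22), hypoxia, immediate early and endothelial genes fell. Of 12 hypoxia and glycolysis genes 4 fell, with the glycolytic genes PGK1 (-0.49 ± 0.08, adjusted p = 0.000908) and ENO1 (-0.25 ± 0.06) and the mitophagy gene BNIP3 (-0.45 ± 0.08), and this list kept its camera call (adjusted p = 9.98e-06; adjusted p = 0.0240 with an estimated correlation). Of 9 immediate early and heat shock genes 5 fell, with DNAJB1 (-0.96 ± 0.17), FOSB (-0.93 ± 0.20) and EGR1 (-0.50 ± 0.12; camera adjusted p = 1.17e-05, adjusted p = 0.237 with an estimated correlation). Endothelial genes KDR (-0.70 ± 0.16) and EGFL7 (-0.51 ± 0.11) fell (2 of 8; camera adjusted p = 0.0140, adjusted p = 0.240 with an estimated correlation). Other falls were LUM, a proteoglycan gene (-0.45 ± 0.10), and COL6A1 (-0.41 ± 0.10) of the mesenchyme list (2 of 10), VIM of the transition list (-0.60 ± 0.14; 1 of 10). Falls were also seen in CYP11A1, an enzyme of steroid synthesis in the trophoblast list (-1.92 ± 0.50; 1 of 6, camera adjusted p = 0.00899, adjusted p = 0.0633 with an estimated correlation), and in TYROBP of the macrophage list (-3.87 ± 0.87; 1 of 3). Rises were BMP4 (0.48 ± 0.10; 1 of 10 lateral plate genes), KRT7 (0.94 ± 0.21; 1 of 9 amnion genes), TDG, a glycosylase of DNA demethylation (0.57 ± 0.13; 1 of 9), and L1TD1, an epiblast gene (1.62 ± 0.41; 1 of 6). HOX genes as a set were called up by camera (adjusted p = 0.000451; adjusted p = 0.240 with an estimated correlation) without any member passing, and in all 21 lists had no member that passed over all genes, 14 of them none over the list alone either. The immediate early (adjusted p = 0.169) and trophoblast lists (0.843) turned direction in camera with the library code as a term. Outside the lists and under the naming rule, UGT3A1 (4.10 ± 0.44, adjusted p = 1.49e-05), EDN3, an endothelin gene (3.39 ± 0.57), and SLC5A12 (3.04 ± 0.55) rose most, and the immediate early factor gene EGR4 (-4.02 ± 0.63) and the potassium channel gene KCNK17 (-3.70 ± 0.80) fell most.

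In Extraembryonic Mesoderm 248 of 11685 genes passed (75 up, 173 down; 1752 at unadjusted p < 0.05). Cluster 22 took 71 of 74 cells from E20 and cluster 8 took 125 of 194 from E22. UGT3A1 and SLC5A12 are among the leading genes by fold of cluster 8, and KCNK17 of cluster 22. Their slopes may thus follow the share of clusters, which was not separated from change within clusters. Without E22 3 genes passed, and without single E22 libraries 110 (library 33), 116 (31), 117 (28), 123 (30) and 128 (32); without library 41, the only one of E18, 1428 passed. Per embryo 0 genes passed in edgeR (880 at unadjusted p < 0.05), against 93 in limma-voom with the embryo as a block and 707 in the DESeq2 Wald test on libraries. With the library code as a term 68 passed, 15 of them among the 248, and CYP11A1, EGFL7, EGR1 and FOSB turned direction. In this class that fit compares only the embryo of E21 with that of E22.

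Some genes had opposite slopes in Extraembryonic Mesoderm and trophoblast, but these differences did not pass once the embryo or library was a term. In the joint fit without such a term with EVT, 28 of 46 genes called in both had opposite slopes with the difference called, among them VIM (difference -1.28), KDR (-1.25), COL6A1 (-0.92) and EGFL7 (-0.93), all lower in Extraembryonic Mesoderm, and KRT7 (1.25). With CTB, 10 of 19 such genes were opposite, among them EGR1 (-0.70) and EGFL7 (-0.77). With the embryo or the library as a term, only E18 and E20 inform the difference for these pairs. Extraembryonic Mesoderm has 1 library at E18, library 41. The lack of calls in that fit therefore cannot decide whether the 28 and the 10 slopes differ. In the pair with EVT 1079 genes were at unadjusted p < 0.05 with the embryo and 877 with the library, in the pair with CTB 1416 and 718. Of the 28, 14 and 13 kept their sign, and of the 10, 6 and 6. CTB and EVT shared 84 called genes, of which 1 was opposite, and EXMC and CTB 31, of which none was. EXMC and EVT shared 52 (2 opposite), EXMC and Extraembryonic Mesoderm 9 (5 opposite, 4 with the difference called, none with either term; 1030 and 540 genes at unadjusted p < 0.05).

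Functional lists differed between classes. Classes drawn from clusters of the same cells differ by construction, so p-values across classes are descriptive. CRABP1 is itself among the leading genes by fold of the Neural ectoderm cluster, and STMN2 of a cluster of Extraembryonic Mesoderm. HOX genes were lower in CTB (19 of 34 lower, none higher) and EVT (9 lower, none higher). They were higher in Mesoderm (18, none lower), Extraembryonic Mesoderm (17, 1 lower), Neural ectoderm (8, none lower) and Non-neural ectoderm (6, 2 lower). EXMC was mixed (7 higher, 8 lower) and PS and derivative had 1 higher. Of the retinoic acid genes 7 of 9 were lower in CTB and 6 in EVT, and 6 were higher in Extraembryonic Mesoderm, 5 in Mesoderm and 4 in EXMC (1 lower). CRABP1 was highest in Neural ectoderm (967.1 ± 224.5 CPM, SD, 3 libraries; log2 fold 5.22 ± 0.52, adjusted p = 1.22e-14), while CRABP2 (-4.93 ± 0.37) and ALDH1A2 (-6.16 ± 1.23) were lower in CTB. Transition genes were lower in CTB (7 of 10) and EVT (5) and higher in EXMC and Extraembryonic Mesoderm (7 each, 2 lower). Among them VIM (-4.20 ± 0.35) and ZEB2 (-4.50 ± 0.35) were lower in CTB, and EPCAM was higher in Non-neural ectoderm (4.95 ± 0.45; 2074.7 ± 776.7 CPM). Folds in this part are log2 ± SE against the mean of the other classes. Those of HOXA5 (-5.70), HOXC8 (-5.36), HOXB8 (-5.29), ALDH1A2, SPRY2 and MSX1 in CTB, where these genes stood near 0 CPM, depend on the prior count.

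Signalling lists differed between classes by single genes. NOTUM was highest in EVT (1289.3 ± 827.6 CPM; 4.73 ± 0.36) and DKK1 in EXMC (385.1 ± 187.1 CPM; 4.44 ± 0.30), and LEF1 was lower in CTB (-3.30 ± 0.32); of 9 WNT targets 3 were higher in EVT, EXMC and Extraembryonic Mesoderm each. PS and derivative stood out by the BMP target MSX1 (2.48 ± 0.52), the FGF target DUSP6 (2.32 ± 0.63), DLL3 of the NOTCH list (3.37 ± 0.52) and DNMT3B (1.96 ± 0.60). BMP targets were higher in Non-neural ectoderm (5 of 9) and lower in CTB (4, 2 higher), EXMC (4, 1 higher) and EVT (3), with MSX1 lower in CTB (-5.40 ± 0.50) and ID2 in EVT (-2.46 ± 0.33). FGF targets DUSP6 (-4.44 ± 0.36) and SPRY2 (-4.81 ± 1.49) and NOTCH genes JAG1 (-3.30 ± 0.48) and HEY1 (-2.79 ± 0.36) were lower in CTB (2 of 7 and 5 of 8 lower). Of 4 NODAL targets CER1, an antagonist of NODAL and WNT, was higher in EVT (3.73 ± 0.87). Its level there was 32.3 ± 119.5 CPM (SD, 21 libraries), so it was very uneven between libraries. Endoderm, EPI, STB and Blood cells were not in these contrasts, and pooled Endoderm cells of E18 held far more CER1 (under Other observations). Hedgehog genes were higher in Mesoderm (3 of 7), GLI1 (3.05 ± 1.008) and HHIP (3.02 ± 0.78) among them, and HHIP also in Extraembryonic Mesoderm (2.98 ± 0.64).

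Growth and stress lists also differed between classes. Proliferation genes were higher in CTB (5 of 12, none lower) and lower in Extraembryonic Mesoderm (7) and EXMC (6), with RRM2 lower in Extraembryonic Mesoderm (-1.40 ± 0.27), CCNB1 higher in EVT (1.84 ± 0.26) and TOP2A in Neural ectoderm (1.76 ± 0.57). DNMT1, the maintenance methyltransferase, was higher in CTB (1.68 ± 0.16) and UHRF1 lower in EVT (-1.22 ± 0.39). Immediate early genes were higher in EXMC (9 of 10) and Extraembryonic Mesoderm (8), with JUNB (3.31 ± 0.31 and 2.56 ± 0.34), and EGR1 was lower in PS and derivative (-2.84 ± 0.62). Of 12 hypoxia genes 7 were lower in CTB, 7 in EXMC (4 higher) and 6 in EVT (3 higher), while CA9, a hypoxia-induced carbonic anhydrase, was lower in CTB (-2.84 ± 0.37) and EVT (-2.50 ± 0.40) and higher in Neural ectoderm (2.78 ± 0.63). The p53 list was higher in EXMC (7 of 10), with GADD45B lower in CTB (-2.82 ± 0.35), the pro-apoptotic gene BBC3 higher in Neural ectoderm (3.34 ± 0.88) and AEN lower in Non-neural ectoderm (-2.62 ± 0.65). Neuronal genes were few (4 tested): TUBB3 was higher in Neural ectoderm (4.28 ± 1.18) and lower in EVT (-3.35 ± 0.83), and STMN2 was higher in Extraembryonic Mesoderm (4.20 ± 0.95).

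Of 154 functional list genes, 60 were higher in Extraembryonic Mesoderm, 49 in EXMC, 37 in Mesoderm, 25 in Neural ectoderm, 19 in Non-neural ectoderm, 17 in CTB, 15 in EVT and 9 in PS and derivative, and 17, 34, 3, 4, 7, 62, 40 and 5 were lower. PS and derivative rests on libraries 5 to 7 of the embryo E16-2, since libraries 1 to 4 hold no other class with 10 cells and add nothing under the block. Neural ectoderm rests on 3 libraries of 1 embryo, and its called genes fell from 29 to 16 without library 30 or library 32. With sums per embryo 35 of the 43 named pairs of gene and class kept the call, and MSX1, DNMT3B and DUSP6 in PS and derivative, UHRF1 in EVT, HHIP and GLI1 in Mesoderm and BBC3 and TOP2A in Neural ectoderm lost it. In PS and derivative 95 genes passed without the library block in place of 14.

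**Figure D4:**
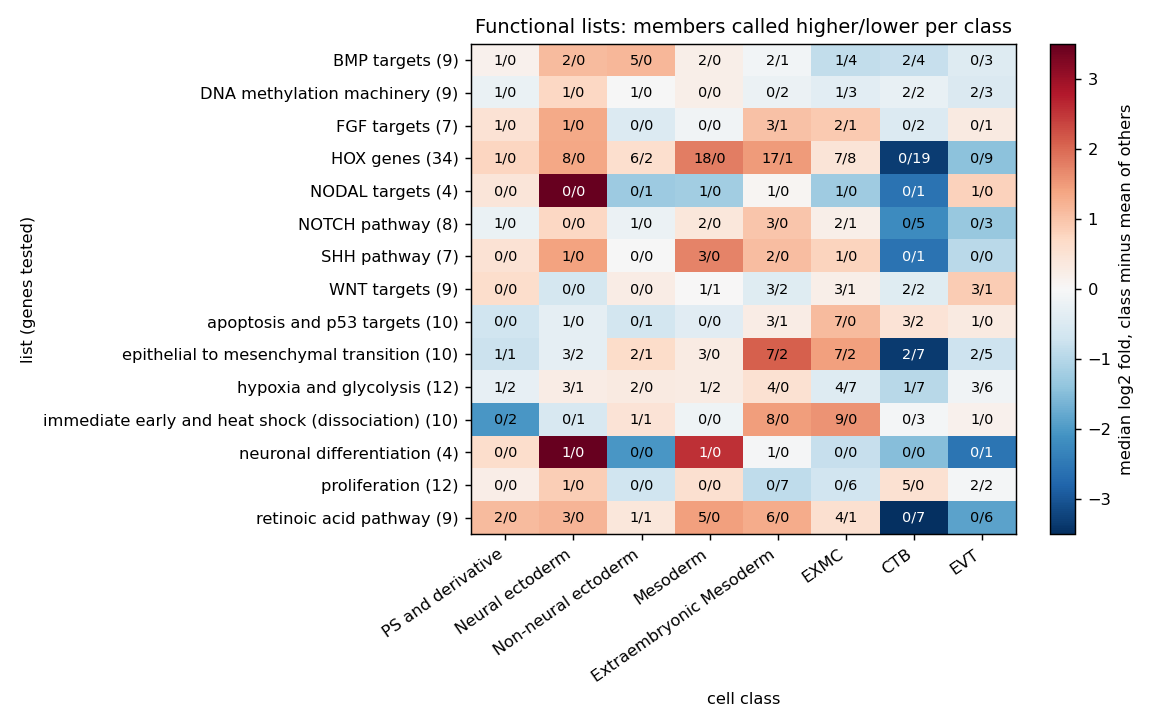
Functional lists (y axis) in 8 classes (x axis): shade is the median log2 fold of the members against the mean of the other classes, and the numbers are members higher and lower. HOX genes have a median of -3.33 in CTB and 1.80 in Mesoderm.

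Marker genes in the class sums describe the names that the authors gave, which may rest on the same genes, so they carry no test, and the genes here were chosen after their values were seen. PS and derivative had MIXL1 at 425.4 ± 150.5 CPM, WNT8A at 142.9 ± 77.3 and EOMES at 106.1 ± 28.9. Neural ectoderm had ZIC2 at 102.3 ± 68.6 CPM and SOX2 at 29.9 ± 18.4, and Non-neural ectoderm had VTCN1 at 450.5 ± 177.8 and GABRP at 303.6 ± 112.0. COL3A1 stood at 14291 ± 4544 CPM in EXMC and 9842 ± 2412 in Extraembryonic Mesoderm, POSTN at 2515 ± 1131 CPM in Extraembryonic Mesoderm and 395.0 in EXMC, PAGE4 at 4575 ± 2683 in CTB and GCM1 at 249.2 ± 117.6 in EVT. HAND1, a mesoderm and amnion factor, had 638.0 ± 214.3 CPM in PS and derivative.

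A DNA library was named for 1862 of the 3682 cells (50.6%, exact interval 48.9 to 52.2). Pairing was unequal between classes: all 228 PS and derivative, 121 Non-neural ectoderm and 17 blood cells were paired, 98.3% of Neural ectoderm and 88.3% of Mesoderm, but 22.9% of EXMC (20.5 to 25.4), 36.1% of CTB and 38.2% of Extraembryonic Mesoderm. Between embryos it ran from 19.3% in E25 and 27.8% in E21 to 78.6% in E22 and 99.0% in E16-1. EVT cells without a DNA library (66.4% had one) had a median of 12715.5 counts, against 119714 in those with one.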

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

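Of the tests in this part, the one on depth in the E16 embryos was set before its result was seen; the other tests of explanations, the shuffles of days and classes and the sums without single clusters were chosen only after the results were seen. Single libraries stood far from the others of their day in 18 of 93 groups tested (19.4%), where chance is taken to mark about 1 in 20 groups; that rate was not measured here and does not hold where all others of a group are listed at 0, so that any count marks a library. By number of cells these were library 44 of E18 with 22 cells (others 82 to 96), library 39 of E20 with 67 (84 to 93) and library 22 of E25 with 85 (92 to 94). By quality they were library 12 of E23 with a median of 3391 genes per cell (4399.5 to 4920) and 13.9% mitochondrial counts (8.25 to 9.90), and library 14 of E25 with 6.76% (4.07 to 4.6). By share they were library 12 with 7.45% CTB (21.7 to 30), library 38 of E20 with 53.6% EVT (23.3 to 32.3) and library 13 of E23 with 11.6% STB (3.26 to 5.95). By gene they were library 4 of E16 with LHX1 at 558.5 CPM (13.2 to 227.3), library 33 of E22 with OGN at 37.2 CPM (11.2 to 18.8). WNT8A stood at 1.06 CPM in library 35 of E20, 2.42 in library 25 of E21 and 0.903 in library 17 of E25 (all others of these days listed at 0) and 8.03 in library 32 of E22 (0 to 2.24). EOMES stood at 0.341 CPM in library 35 and 0.903 in library 17 (others listed at 0) and 0.911 in library 28 of E22 (0 to 0.119).

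The E16 embryos differed in the share of PS and derivative cells, with 90.9% in E16-1 and 13.6% in E16-2. Depth per cell is argued against: among cells above 100000 counts the gap was 76.1 percentage points (89.0% of 100 cells and 12.9% of 163). A single mislabelled library is argued against as well, since the lowest library of E16-1 (82.1%) and the highest of E16-2 (17.2%) lie 64.9 points apart. The part of the embryo taken at dissection or by the pipette stays open: extraembryonic and trophoblast classes made up 4.33% of E16-1 and 84.6% of E16-2, and nothing in the tables separates what was taken from what the embryo held. A difference in stage between the embryos may also account for it and was not tested. By the annotation E16-1 is male and E16-2 female, and sex was not tested either.

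Mesenchymal genes rose with day in EVT, and RNA or cells of the mesenchyme in the EVT sums could account for much of this. The EXMC genes stood at a near common fraction of their EXMC level in E23, E24 and E25, with upper over lower quartile at most 1.84. The ratio was 1.83 in E18, 2.79 in E20 (164 cells), 1.59 in E21 and 4.26 in E22 (9 cells), and 2.07 in E25 without cluster 18. The limit of 2 for this ratio was set after fractions had been seen, and CTB shows a similar ratio (1.86). An earlier form of the test on cluster 18 alone (1.37) was replaced. Cluster 18 is not the whole source, since without it EVT stood at 21.6% of the EXMC level in E23 (144 cells) against 2.21% in E18, and the median slope of the mesenchyme list was 0.48. That slope rests on E18 to E24, because no library of E25 keeps 10 cells, and compares with 0.44 for all EVT cells without E25 (0.51 with all days); 2 of the 10 members then passed in place of 9. Of the EVT cells of E23, 130 are in cluster 7, whose cells had a median of 10199.5 counts, 1219.5 genes and 18.3% mitochondrial counts. The other EVT clusters had medians of 77731 to 336667 counts. Whether this low depth raises the level in E23 was not tested. In E25 most of the level lies in cluster 18, whose 36 cells stood at 53.6% of the EXMC level (quartiles 46.5 to 61.5) against 9.62% in the other 12 (6.75 to 13.96). In CTB the same genes stood at 7.54% in E16-2, 1.44% in E18, 1.54% in E24 and 5.78% in E25, with no steady rise. They were chosen for a low level in CTB in E24 and E25, so that low level is no result. RNA of the mesenchyme was not tested as a source of OGN and COL8A1 in CTB. Doublets of 2 whole cells in cluster 18 stay open too: its cells held 0.624 times the counts of other EVT cells in E24 and E25 pooled, but 0.515 times in E24 and 1.29 times in E25, where 12 other cells remain. The median level of 36 EVT genes in cluster 18 was 21.5% of that in other EVT cells of E24 and E25. These genes were chosen in the same cells, with at least 500 CPM in other EVT cells and at least 10 times the EXMC level. Their lower level in cluster 18 is therefore partly set by the choice. A biological change of EVT toward a mesenchymal state was not tested.

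The numbers of genes with a day slope were larger than in shuffles of days over libraries, but not larger than differences between embryos allow. With days shuffled over libraries, 1 of 100 assignments, the real one, gave as many genes in each of the 5 trends. The real counts were 2435 in all cells against at most 2 in another shuffle, 190 in EXMC against 4 and 363 in CTB against 11. In EVT they were 677 against 11 and in Extraembryonic Mesoderm 248 against 182. This shuffle parts libraries that share an embryo, so it cannot exclude chance differences between embryos. With days shuffled over whole embryos as many genes passed in 26 of 100 assignments for all cells (highest other 4402), in 67 for EXMC (1389), 62 for CTB (2153), 22 for EVT (1660) and 15 of 24 for Extraembryonic Mesoderm (1947), so differences between embryos in no order of day could give such counts. Assignments that call several times the real count, as in EXMC, CTB and Extraembryonic Mesoderm, point to a structure of the samples, here the embryo that libraries share. Sums per embryo set the slope against the spread between embryos. With them 10 genes passed in EVT and 0 in all cells, EXMC, CTB and Extraembryonic Mesoderm. A course of development over these days stays open, since each day after E16 holds 1 embryo and its effect cannot be told from that of its day.

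For the classes, 445 functional list calls were made with the adjustment over the list genes alone, and 1 of 100 assignments of classes within libraries, the real one, gave as many (highest other 6). This decides nothing on chance, since classes drawn from clusters of the same cells differ in expression by construction. Slopes that differed between classes in the joint fit without a term for embryo or library were EGR1 (-0.70, adjusted p = 0.000592) and EGFL7 (-0.77, adjusted p = 0.00481) in Extraembryonic Mesoderm minus CTB, and KRT7 (1.25, adjusted p = 0.00260), COL6A1 (-0.92, adjusted p = 0.00385), VIM (-1.28, adjusted p = 0.00672), KDR (-1.25, adjusted p = 0.0132) and EGFL7 (-0.93, adjusted p = 0.0265) in Extraembryonic Mesoderm minus EVT. None of these 7 kept its call with the embryo or the library as a term (adjusted p from 0.407 to 0.978). The days of these classes differ, since Extraembryonic Mesoderm ends at E22 in this test. Under either term only E18, with 1 library of Extraembryonic Mesoderm, and E20 remain, so the lost calls do not decide whether the slopes differ. The 2 libraries outside the groups also held cells of the classes: EXMC made up 31 of the 55 cells of library 26 (56.4%) and EVT 34 of the 94 cells of library 27 (36.2%).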

How the results depend on the processing

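The code of the cell names, the embryo as a block, sums or shares per embryo, the embryo or library as a term in the joint fit of 2 classes, sums without a fine cluster and class contrasts without single Neural ectoderm libraries or without PS and derivative were tests chosen only after the data were seen; the others were set earlier. Days cannot be paired, because replicate numbers are unique to each library. Class contrasts had the library as a block. The joint fits of slopes had none at first and were run again with the embryo or the library as a term. Early against late days could not be run for Extraembryonic Mesoderm, which has no late libraries. Libraries, days and depth together limit what can be called: the self-test on the sums of Extraembryonic Mesoderm recovered 12% of slopes of 0.5, and of EVT 25% of slopes of 0.25. Thinning cells to 10000 counts left 1757 genes in all cells in place of 2435. It also left out 200 cells, so it does not test depth by itself. Apart from leaving out libraries, 40 counts of genes with a slope stayed within 1.5 times and 52 moved further. Of the class shares 160 kept direction and side of the threshold, 30 changed direction, 8 lost the call and 2 gained it. Of the named slopes 1974 kept both, 828 lost the call and 49 changed direction. Of the named pairs across classes 229 kept both and 12 lost the call. Of counts of list members 870 stayed and 604 moved; of single list calls 41 stayed, 54 were lost and 5 changed direction. The cause of these changes was not tested.

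Counts of genes with a slope moved as follows. The DESeq2 Wald test called 388 in EXMC, 795 in CTB, 1175 in EVT and 707 in Extraembryonic Mesoderm, and no filter on low counts 1008, 1200 and 2047 in EXMC, CTB and EVT. At least 20 cells per library gave 337, 2508, 1403 and 541 in the 4 classes, at least 5 cells 66 in Extraembryonic Mesoderm, and the unassigned libraries added by title 77 there. Early against late days gave 1138 in CTB and 1156 in EVT. The library code as a term gave 1009 in all cells, 472 in EXMC, 83 in CTB, 63 in EVT and 68 in Extraembryonic Mesoderm, as a random block in limma-voom 970, 731, 15, 315 and 58, and the code of the cell names as a term 1311 in all cells and 735 in EXMC. The embryo as a random block in limma-voom gave 197, 126, 12, 230 and 93, and sums per embryo 0, 0, 0, 10 and 0 in edgeR (1412, 372, 713, 991 and 880 at unadjusted p < 0.05). Without E16 1089 passed in all cells, 55 in EXMC and 747 in CTB. Without E18 728 in EXMC, 948 in CTB, 1542 in EVT and 1428 in Extraembryonic Mesoderm. Without E20 342 in EXMC, 226 in CTB and 273 in EVT; without E21 125 in EXMC; without E22 3 in Extraembryonic Mesoderm; without E25 72 in CTB and 94 in EVT. Without cluster 18 91 passed in EVT.

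Leaving out 1 library at a time gave 73 to 237 genes in EXMC, 184 to 747 in CTB, 387 to 813 in EVT, 110 to 1428 in Extraembryonic Mesoderm and 1902 to 2570 in all cells, and rho of the Extraembryonic Mesoderm share from -0.00925 to 0.102. The lows are without library 5, 17, 17, 33, 4 and 1. Functional calls in Neural ectoderm ran from 16 (without library 30 or 32) to 24. Camera called no list with an estimated correlation in all cells, EXMC, CTB and EVT (0 each, against 12, 4, 4 and 5, and 17, 3, 10 and 6 by fry) and 1 in Extraembryonic Mesoderm. Fry called 10 lists in CTB, the library code as a term gave 7 in EXMC, 0 in CTB, 0 in EVT and 1 in Extraembryonic Mesoderm, and sums per embryo 0 in CTB and 2 in Extraembryonic Mesoderm. With the library code as a term the direction changed for extraembryonic mesenchyme (adjusted p = 0.942) and proliferation (0.595) in all cells, epithelial to mesenchymal transition in CTB (0.941), and immediate early and heat shock (0.169) and trophoblast (0.843) in Extraembryonic Mesoderm. Class contrasts with at least 20 cells hold 5 classes; PS and derivative has no value there because it shares no library with another class, and the ectoderm classes keep too few libraries. Functional list calls moved to 44 in EXMC with at least 20 cells, to 85 in EVT, 54 in Neural ectoderm and 95 in PS and derivative with no library block, and to 35 in EVT, 16 in Mesoderm, 15 in Neural ectoderm, 10 in Non-neural ectoderm and 9 in PS and derivative with sums per embryo.

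Relations of class shares with day (rho) changed direction or side as follows. Log odds gave -0.165 for Blood cells and -0.282 for Neural ectoderm, and at least 40 cells per library -0.00807 for Extraembryonic Mesoderm. Shares per embryo gave 0.00851 for Endoderm, -0.0696 for Neural ectoderm, and 0.594 for Non-neural ectoderm and -0.651 for PS and derivative, which lost the call. Without E16 values were -0.0923 for Blood cells, -0.0585 for CTB, -0.0967 for EVT, -0.431 for Extraembryonic Mesoderm, -0.257 for Mesoderm, -0.0399 for Neural ectoderm and -0.0328 for PS and derivative. Without E18 they were 0.0150 for EPI, 0.139 for Endoderm and -0.00645 for Extraembryonic Mesoderm. Without E20 values were 0.515 for CTB and 0.507 for EVT, which gained the call, and -0.0495 for Mesoderm. Without E22 the value was -0.0673 for Neural ectoderm; without E23 0.0268 for Endoderm and -0.0609 for STB; without E25 -0.0422 for EXMC. Without the 2 libraries farthest from the median day they were -0.0755 for Extraembryonic Mesoderm and -0.00826 for Mesoderm. Within code 20210308, where no relation could pass, they were -0.612 for EXMC, 0.255 for Endoderm and -0.412 for STB, with the call lost for Non-neural ectoderm (0.612) and PS and derivative (-1.0). Within code 20210727 they were 0.553 for EPI, -0.310 for Extraembryonic Mesoderm and -0.553 for Mesoderm, with the call lost for Non-neural ectoderm (0.796). Within code 20210820 they were -0.250 for CTB, -0.251 for EVT and -0.361 for EXMC, with the call lost for Non-neural ectoderm (0.429) and PS and derivative (-0.292).

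Slopes of named genes changed direction with the library code as a term for COL1A1 (-0.0151), COL6A1 (-0.0214), DNMT3B (0.00959), FGG (-0.33), FOXA3 (0.10) and TF (-0.35) in all cells. In single classes they changed for CDH5 (0.73), EGFL7 (-0.0124) and EPCAM (-0.93) in CTB, CRABP1 (-1.19), DKK1 (-0.16), GADD45B (-0.36), LEF1 (-0.28) and RRM2 (0.76) in EVT, and CYP11A1 (0.75), EGFL7 (0.0852), EGR1 (0.21) and FOSB (0.96) in Extraembryonic Mesoderm. With the code of the cell names they changed for BAX (0.00329), COL1A1 (-0.0339), COL6A1 (-0.12), DNMT3B (0.23), EGFL7 (-0.00507), ETV4 (0.22), FGG (-1.03), FOXA3 (0.10), IGFBP3 (-0.0213), MESP1 (0.0873), PCNA (0.0623), RARB (-0.0387), TCF21 (-0.0104), TF (-0.63), WNT8A (0.25) and ZEB2 (-0.0388) in all cells, and ALDH1A2 (0.0622), PODN (-0.0653), SPP1 (0.0750) and TSHR (-0.17) in EXMC. Without E16 they changed for HOXA3 (0.45), LHX1 (0.00671), MESP1 (0.48), MSX1 (0.12), SALL4 (0.00394) and WNT8A (0.36) in all cells, and HAND1 (0.0507), MIXL1 (0.13), MYL7 (0.19) and SPP1 (0.00691) in EXMC. At least 20 cells per library turned ABCC3 in CTB (0.38). With a term in the joint fit of 2 classes, the difference of Extraembryonic Mesoderm minus CTB turned for EGFL7 (0.0990 with the embryo, 0.38 with the library). That of Extraembryonic Mesoderm minus EVT turned for VIM (0.0778 with the embryo) and EGFL7 (0.40 with the library). The other 10 of these 14 values lost the call. Opposite slopes with the difference called fell to 0 with either term in Extraembryonic Mesoderm against EVT, CTB and EXMC (28, 10 and 4 without). They went to 2 and 1 in EXMC against EVT (2) and stayed at 1 in CTB against EVT.

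Leaving out 1 library ended the call of some named genes and turned none (4411 kept, 213 lost); each is given with the library that gave the highest adjusted p and that p, and the number of such libraries where above 1. In all cells these were CSF1R (21, 0.0708), CXCR4 (4, 0.0517), DUSP6 (4, 0.0664), FGG (12, 0.0550), TF (28, 0.0603), IGFBP3 (4, 0.0575, 5 libraries) and LHX2 (21, 0.117, 10 libraries). In EXMC they were MIXL1 (6, 0.199), PODN (5, 0.0546), NOTUM (7, 0.0675, 2 libraries), TCF21 (5, 0.101, 3 libraries), TSHR (5, 0.0930, 3 libraries), HAND1 (6, 0.188, 5 libraries), ALDH1A2 (5, 0.0940, 6 libraries) and MYL7 (7, 0.252, 18 libraries). In CTB they were EGFL7 (17, 0.0709), CCNA2 (17, 0.0686, 4 libraries), FKBP5 (40, 0.0839, 6 libraries), MAPK12 (17, 0.0663, 6 libraries), CA3 (39, 0.0638, 8 libraries), COL8A1 (40, 0.0629, 8 libraries), MKI67 (17, 0.101, 15 libraries) and PPBP (17, 0.102, 17 libraries). In EVT they were BMP4 (17, 0.0637), HAND2 (22, 0.0543), SESN1 (17, 0.0543), EGFL7 (22, 0.0725, 3 libraries), P4HA1 (17, 0.0979, 4 libraries), LEF1 (17, 0.0775, 5 libraries), GCM1 (17, 0.0876, 6 libraries), GADD45B (22, 0.0867, 9 libraries) and CCNB1 (22, 0.0841, 10 libraries). In Extraembryonic Mesoderm they were TYROBP (36, 0.0511), EGR1 (28, 0.0510, 2 libraries), KRT7 (31, 0.0582, 2 libraries), LUM (31, 0.0543, 2 libraries), VIM (31, 0.0589, 3 libraries), L1TD1 (28, 0.117, 8 libraries), ENO1 (31, 0.0785, 9 libraries), COL6A1 (30, 0.0898, 11 libraries) and CYP11A1 (30, 0.0837, 11 libraries).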

Other observations

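No test was run in this part, and all levels in it were looked at after the classes had been seen; they are CPM of the pooled cells of a class in 1 embryo, with counting error only and no replicate. Epiblast cells of E18 (23 cells) held the germ cell gene NANOS3 at 13.01 CPM, found in 5 cells, SOX17 at 21.2 and SOX15 at 93.8, beside the pluripotency factor gene NANOG at 227.7. In E21 (15 cells) NANOS3 stood at 4.61, SOX17 at 19.03 and NANOG at 286.1, and in E25 (15 cells) NANOG stood at 140.0 while NANOS3 and SOX17 had no count, which allows up to 0.933. The epiblast cells of E16-2 (5 cells) had no count of NANOG, which allows up to 4.596, and carried the amnion genes TFAP2A (157.8), GABRP (154.7) and ISL1 (142.5); those of E23 (8 cells) had TFAP2A at 227.1 and ISL1 at 82.9.

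Endoderm cells differed in content between embryos. In E18 (26 cells) the anterior endoderm gene CER1 stood at 2770.7 CPM, GDF3 at 1323.9 and DPPA3 at 390.9, the last found in 23 cells; CER1 stood at 320.6 in E21 (18 cells), and had no count in E22 (8 cells), which allows up to 2.53. The yolk sac genes AFP and TF stood at 115.1 and 8.54 in E18, 747.3 and 1422.5 in E21, and 3935.4 and 2616.3 in E22, while the apolipoprotein gene APOA1 was high in all of these (14133.8, 8632.6 and 9606.8). Neural ectoderm of E22 (57 cells) held ZIC2 at 94.1 CPM (39 cells) and ZIC1 at 55.1 (18 cells), NES at 66.7 and PAX6 at 8.06 (6 cells); OTX2 stood at 2.64, and SOX1, EN1 and SIX3 had no count, which allows up to 0.440. Blood cells of E20 (5 cells) held the leukocyte gene PTPRC at 163.9 and the myeloid factor gene SPI1 at 79.9, which had no count in E22 (6 cells, up to 2.71) or E23 (4 cells, up to 2.48), whereas the endothelial and platelet gene PECAM1 was found in all of these (492.7, 479.5 and 786.8). The embryonic globin gene HBZ and GATA1 had no count in any of these embryos, which allows up to 1.55 in E20. Non-neural ectoderm held GABRP at 168.7 and VTCN1 at 144.5 in E22 (47 cells) and 232.1 and 438.2 in E23 (68 cells), and TP63, a factor of surface epithelium, at 25.5 and 2.47.

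Labels of 2 libraries named 2 days each. Library 26 is E24 by title and E21 by time label and by the annotation of its cells; it held 31 EXMC cells, 13 of Extraembryonic Mesoderm, 3 Endoderm, 3 EPI, 2 CTB, 2 EVT and 1 Mesoderm. Library 27 is E22 by title and E24 by time label and annotation, and held 34 EVT, 27 CTB, 17 EXMC and 11 STB cells, 2 of Extraembryonic Mesoderm, 2 Endoderm and 1 EPI.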
